A study of Mus musculus with 9 samples.

How the data were processed

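Whole testis of male Swiss albino mice aged 8, 16 and 24 days was profiled on 9 arrays, 3 per age. Per the labels, total RNA was extracted with QIAzol and a miRNeasy kit and labelled with biotin by the Affymetrix whole-transcript sense-target protocol. The array type, MoGene 1.0 ST, is known only from a comment in the probe table. The deposited values are log2 values of 28815 rows, which the authors gave relative to each row's median over the 9 arrays, from -6.07 to 6.05. How signals were background corrected, normalized, summarized and centred is not given in the sources used here.

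Each row had at least 1 blank cell, 38964 in all. With blanks taken as 0 the median of every row was 0, and all 21932 rows with a single blank had 4 values on each side of 0. Blanks were therefore taken as 0, the value of the median array. The other 6883 rows had 2 to 8 blanks, which held 10149 cells beyond the first of a row, 4.4% of the other cells. As an alternative all 38964 blanks were left missing, also the single blank of a row. Because the values are centred, they give no expression level, no detection limit and no filter on dim genes, and the number of arrays limits the precision.

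Of the 28815 rows, 21780 carried exactly 1 gene symbol, 1605 carried several and 5430 had no gene. The gene IDs of 21689 single-gene rows matched a RefSeq gene table (GRCm38.p6), which was used only for names and for which chromosome a gene is on. No build is named with the array values, so no coordinates are given. Rows of the same gene were averaged, which left 19935 genes, 998 of them with more than 1 row. The rule fixed in advance was to take the row with the highest mean, which has no meaning for centred values, so that the mean of the rows took its place and the highest-mean row was tried as an alternative. Rows with several genes or none stayed out of the gene test.

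Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, a mean per age, all 9 arrays, 6 residual and 3.82 prior degrees of freedom). Contrasts were 16 minus 8, 24 minus 16 and 24 minus 8 days, the difference between the second and the first interval, and a moderated F over the 3 ages. All tests were 2-sided, and p was adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. The comparisons, tests, thresholds, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Replicate numbers were not used as a block, since no label says that they pair samples.

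There were 27 lists of genes from textbook knowledge of testis cell types, germ cell stages and pathways, with 506 measured genes, 24 of them in more than 1 list. The 26 lists with at least 5 measured genes were tested by camera with a preset correlation of 0.01, with a correlation estimated from the data, and by fry. Members called are counted after adjustment over all genes and adjusted over the list alone. The genes of chromosome X were tested by camera as 1 set. List medians are relative to the median of all genes in the comparison, which was -0.02, -0.16 and -0.18 for 16 versus 8, 24 versus 16 and 24 versus 8 days. Centring each array on its median over all genes shifted these comparisons by 0.03, 0.09 and 0.12.

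Named genes are the 6 largest rises and 6 largest falls per comparison among called genes whose arrays did not overlap, leaving out unnamed genes and multicopy families, the up to 3 members of each list with the largest called change, and 12 stage genes. Of the list members that this rule gives, those whose call was lost when 1 array was left out are mostly not printed, a choice made after the values were seen. Errors of changes are limma's moderated standard errors, and errors of means are SD.

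On simulated data for 16 versus 8 days with 19935 genes, the test recovered 31.3% of genes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 95.5% of those changed by 2, and called 8 of 19735 unchanged genes. Of 20 simulated lists, the 1 shifted list was called and the others were not. The simulated genes were independent of each other, so that this does not test lists of correlated genes.

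The alternatives were each array centred on its median, the row with the highest mean, all rows, array weights, only the arrays of the ages compared, a 2-fold minimum, limma treat against 1.5-fold, replicate blocks, and each array left out in turn. Alternatives added after seeing the data were blanks left missing, only rows with 1 blank, robust eBayes, a covariate from 1027 olfactory receptor genes, leaving out the 2 arrays in which those genes were high, and 10000 random lists of the same size. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.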

Results

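Gene expression was measured in whole testis of male Swiss albino mice aged 8, 16 and 24 days, with 3 arrays per age and 9 arrays in all. These ages fall in the first wave of spermatogenesis, when germ cells advance together and the most advanced germ cell type present changes with age. The design text states that the 3 arrays of an age are biological replicates and names 3 comparisons, 16 with 8 days, 24 with 16 days and 24 with 8 days. The deposited values were log2 values relative to each array row's median over the 9 arrays, so they show differences between ages and hold no absolute expression level. In whole testis, a change within cells cannot be told apart from a change in the share of a cell type. In total 19935 genes had a value. The number of arrays limits the precision. Replicates 1 and 2 are the arrays whose titles carry those numbers, and replicate 3 is the array whose title carries none.

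Of the genes chosen in advance to mark stages, the spermatogonial and Sertoli cell genes were lowest at 24 days, the meiotic genes had risen by 16 days and the haploid genes rose between 16 and 24 days. Relative to each gene's median, the mean of Piwil1 (gene ID 57749), which encodes a PIWI protein of pachytene spermatocytes, was -3.61 ± 0.12, 0.07 ± 0.21 and 0.36 ± 0.17 at 8, 16 and 24 days (SD, n = 3). For Ldhc (gene ID 16833), the lactate dehydrogenase of germ cells, the means were -4.81 ± 0.11, 0.09 ± 0.19 and 0.81 ± 0.07. Prm1 (gene ID 19118), a protamine that replaces histones in spermatids, had means of -0.04 ± 0.10, -0.12 ± 0.11 and 4.95 ± 0.55. Amh (gene ID 11705), the anti-Mullerian hormone of immature Sertoli cells, had means of 1.66 ± 0.60, -0.05 ± 0.22 and -0.70 ± 0.18. Insl3, also chosen in advance, had no row of its own on the array and is not analysed here.

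**Figure D1:**
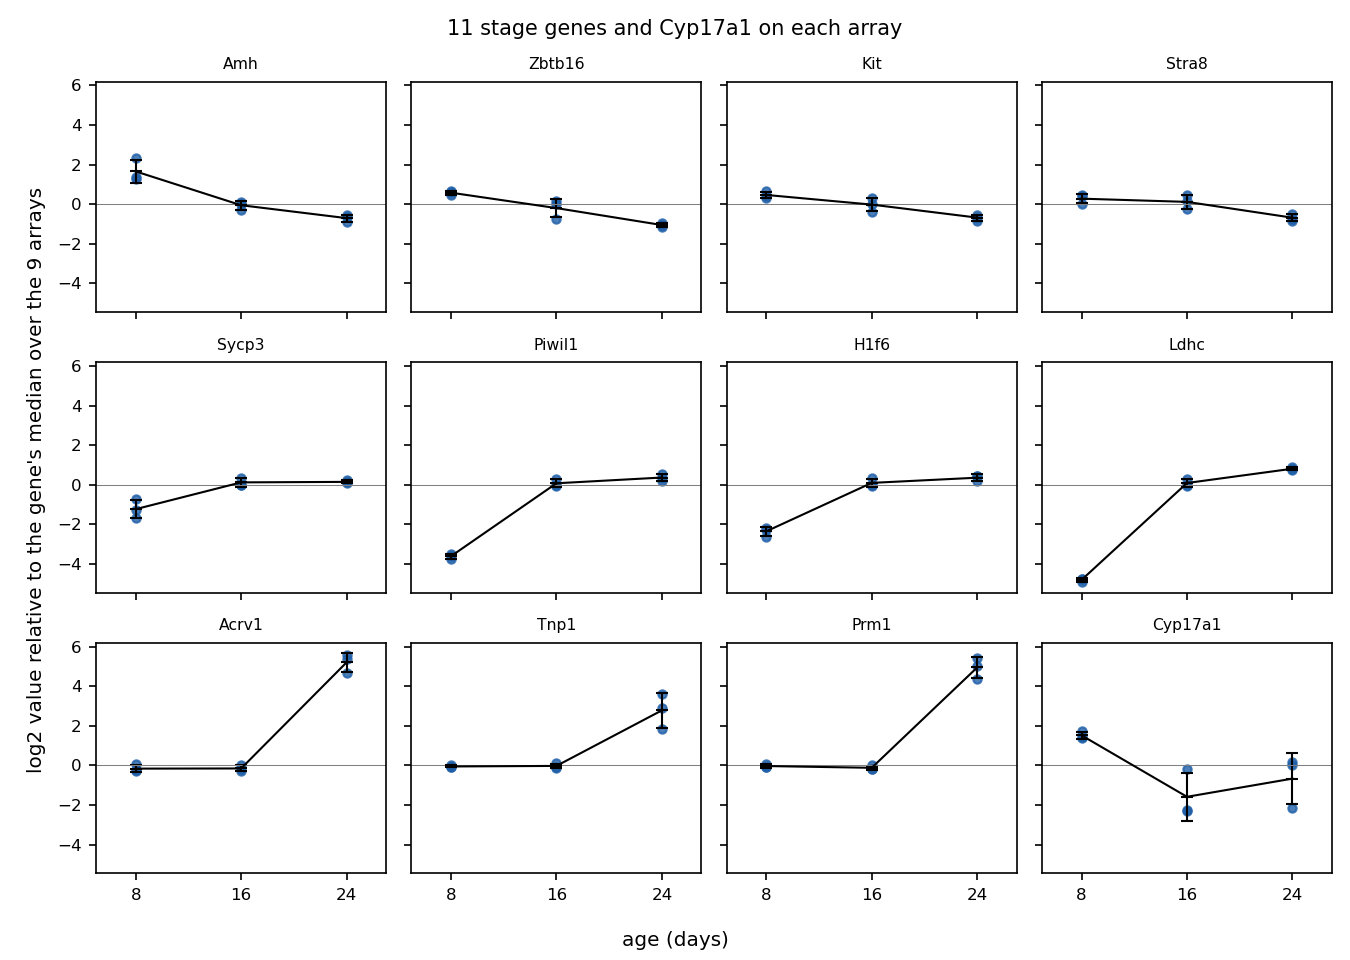
Log2 value relative to the gene's median over the 9 arrays (vertical axis) against age in days (horizontal axis) for 11 stage genes and Cyp17a1. Blue points are arrays, and black marks are the mean and SD of 3 arrays; the mean of Prm1 was -0.12 ± 0.11 at 16 days and 4.95 ± 0.55 at 24 days.

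Between 8 and 16 days, genes of spermatocytes rose by up to 65.5-fold, and genes of steroid synthesis, prenatal growth and matrix fell. The 6 largest rises among named genes were those of Crisp2 (gene ID 22024), a cysteine-rich secretory protein of sperm, by 6.03 ± 0.16 on the log2 scale (standard error, 3 arrays per age), Spata4 by 6.02 ± 0.13, the glycerol kinase isoform Gk2 by 5.68 ± 0.18, the sperm fatty acid-binding protein Fabp9 by 5.45 ± 0.10, the fructose bisphosphatase Fbp1 by 5.22 ± 0.15, and Ube2d2b, a ubiquitin-conjugating enzyme, by 5.11 ± 0.16. Their limma adjusted p lay between 4.14e-09 and 5.40e-08. Among the largest falls, Cyp17a1 (gene ID 13074), the enzyme that leads into androgen synthesis, fell by 3.10 ± 0.66, or 8.60-fold, and Cyp11a1, which starts steroid synthesis from cholesterol, fell by 2.42 ± 0.36. The Cyp17a1 values at 16 days were -2.25, -0.20 and -2.32 in replicates 1, 2 and 3, and its change ranged from -3.80 without replicate 2 to -2.74 without replicate 3 of 16 days. The imprinted genes Mest and Zim1 changed by -2.40 ± 0.20 and -2.18 ± 0.23, Sel1l3 fell by 2.29 ± 0.16 and Lpcat2, a lysophospholipid acyltransferase, fell by 2.20 ± 0.18.

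Several groups of spermatocyte genes fixed in advance rose at 16 days. Group medians are given relative to the median of all genes in the same comparison. Of 25 pachytene spermatocyte genes, 21 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 2.12, and the camera adjusted p was 9.54e-25 (adjusted p = 0.0529 with an estimated correlation). Besides Crisp2, Ldhc rose by 4.89 ± 0.11 and Adam2, a sperm surface protein, rose 24.3-fold. Of 36 genes of the meiotic chromosome axis, synapsis and recombination, 26 rose and 1 fell (26 and 3 adjusted over the list alone), with a median of 1.04 (adjusted p = 0.0996 with an estimated correlation). Spo11, which makes the double-strand breaks of meiosis, rose by 2.90 ± 0.17, the single-strand DNA-binding protein Meiob by 3.39 ± 0.20, its partner Spata22 by 2.71 ± 0.17 and the axis protein Sycp3 by 1.35 ± 0.20. In the piRNA pathway, 17 of 20 genes rose and 2 fell (17 and 2 adjusted over the list alone; median 0.84; adjusted p = 0.119 with an estimated correlation), with rises of 3.69 ± 0.13 for Piwil1 and 3.62 ± 0.23 for the tudor protein Tdrd6. Of 20 metabolic isoforms and retrocopies used by germ cells, 15 rose (16 adjusted over the list alone), with a median of 2.07 (adjusted p = 0.0996 with an estimated correlation). Pabpc2, a poly(A)-binding protein, rose by 5.01 ± 0.22.

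Part of the genes of later germ cell structures had also risen by 16 days. Of 39 flagellum and axoneme genes, 24 rose at either adjustment, over all genes or adjusted over the list alone (median 1.22; adjusted p = 0.164 with an estimated correlation). Rsph1, a radial spoke protein, rose by 3.72 ± 0.12, the outer dense fibre protein Odf4 by 3.58 ± 0.18 and Spag17 of the central pair by 3.58 ± 0.20. Of 23 acrosome genes, 12 rose, as many as adjusted over the list alone (median 0.77; adjusted p = 0.239 with an estimated correlation), among them the serine protease acrosin, Acr, by 2.89 ± 0.17, the protease inhibitor Spink2 by 3.45 ± 0.25 and Zpbp2 by 3.19 ± 0.21. Of 19 transcription regulators of meiosis and spermiogenesis, 10 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.81, or 1.26 with only rows with 1 blank cell; adjusted p = 0.0996 with an estimated correlation). Sox30, a transcription factor of meiotic and haploid germ cells, rose by 2.33 ± 0.10, Mybl1, a regulator of pachytene genes, by 2.18 ± 0.23 and Gtf2a1l, a germ cell form of a general transcription factor, by 2.38 ± 0.14. None of the 23 genes of spermatid chromatin and late haploid transcripts passed the limma test at 16 days, nor did any at an unadjusted p under 0.05, and the group's camera adjusted p was 0.326. The change was 0.03 ± 0.33 for the transition protein Tnp1, -0.09 ± 0.22 for Prm1 and 0.01 ± 0.21 for Acrv1, an acrosomal protein.

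Markers of several somatic cell types fell over the same interval. Of 13 genes of Leydig cells and steroidogenesis, 9 fell, as many as adjusted over the list alone (median -1.17; adjusted p = 0.119 with an estimated correlation), including Hsd17b3, which makes testosterone and fell by 2.18 ± 0.30. Of 19 Sertoli cell genes, 9 fell (12 adjusted over the list alone), with a median of -0.42, or -0.22 without replicate 2 of 16 days (adjusted p = 0.322 with an estimated correlation). Amh fell by 1.71 ± 0.25, the Kit ligand gene Kitl fell by 1.04 ± 0.11 and the inhibin subunit Inhbb fell by 0.96 ± 0.13. Of 12 peritubular myoid genes 8 fell, as many as adjusted over the list alone (median -0.35; adjusted p = 0.167 with an estimated correlation), and of 16 endothelial genes 11 fell (13 adjusted over the list alone; median -0.47; adjusted p = 0.0529 with an estimated correlation). The endothelial cadherin Cdh5 fell by 0.96 ± 0.15, the growth factor receptor Kdr fell by 0.83 ± 0.10 and the smoothelin gene Smtn fell by 0.61 ± 0.09. Of 29 extracellular matrix genes, 22 fell (24 adjusted over the list alone; median -0.64; adjusted p = 0.123 with an estimated correlation), with changes of -1.40 ± 0.15 for periostin, Postn, and -1.11 ± 0.16 for the laminin chain Lamb1.

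Groups of growth, metabolism and stress also fell. Of 15 imprinted genes of prenatal growth, 13 fell (14 adjusted over the list alone; median -1.07; adjusted p = 0.141 with an estimated correlation), and Plagl1, a zinc finger regulator, fell by 2.04 ± 0.27. Of 35 X-linked housekeeping genes, 22 fell (24 adjusted over the list alone), with a median of -0.47, or -0.30 without replicate 2 of 16 days (adjusted p = 0.332 with an estimated correlation). The ribosomal protein Rps4x fell by 1.02 ± 0.17 and the cytoskeletal linker moesin, Msn, fell by 0.90 ± 0.16. Of 19 ubiquitous partners of the germ cell isoforms, 14 fell and 2 rose (15 and 2 adjusted over the list alone; median -0.46; adjusted p = 0.261 with an estimated correlation). The X-linked phosphoglycerate kinase Pgk1 fell by 0.75 ± 0.17, while the lactate dehydrogenase Ldha rose by 1.27 ± 0.14. Of 19 cholesterol synthesis genes 9 fell, as many as adjusted over the list alone (median -0.34; adjusted p = 0.254 with an estimated correlation). With each array centred on its median, falls numbered 17 in the X-linked housekeeping list, 11 among the partners and 7 in cholesterol synthesis. Nsdhl, a sterol dehydrogenase, fell by 0.86 ± 0.14. Of 16 immediate early and heat shock genes 7 fell (8 adjusted over the list alone; median -0.25; adjusted p = 0.121 with an estimated correlation), among them the transcription factor Egr2, which fell by 0.68 ± 0.12.

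Spermatogonial genes were lower at 16 days, with exceptions. Of 19 genes of undifferentiated spermatogonia, 12 fell and 1 rose (13 and 1 adjusted over the list alone; median -0.47; adjusted p = 0.167 with an estimated correlation). Sall4, a zinc finger factor of stem and progenitor cells, fell by 0.72 ± 0.14, and Id4, an inhibitor of DNA binding and a stem cell marker that spermatocytes also express, rose by 1.25 ± 0.09. Zbtb16 (gene ID 235320), a repressor of spermatogonial differentiation, changed by -0.78 ± 0.20, and by -0.51 without replicate 2 of 16 days. Its adjusted p of 0.0155 rose as high as 0.0532, above the threshold, without replicate 2 or replicate 3 of 8 days. Of 15 genes of differentiating spermatogonia, 6 fell (7 adjusted over the list alone), with a median of -0.30 that ranged from -0.50 without replicate 1 of 8 days to -0.18 without replicate 2 of 16 days (adjusted p = 0.397 with an estimated correlation). The cyclin Ccnd2 fell by 1.11 ± 0.14 and the ubiquitin hydrolase Uchl1 fell by 0.86 ± 0.11. The change was -0.49 ± 0.17 for the receptor Kit (adjusted p 0.0602, and 0.0138 without replicate 3 of 16 days) and -0.16 ± 0.19 for Stra8, which is needed to enter meiosis (adjusted p 0.686).

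Over all genes, 4914 of 19935 differed between 16 and 8 days by limma at an adjusted p of 0.05, of which 2071 rose and 2843 fell. At least 2-fold changes were found in 761 that rose and 193 that fell. When each array was centred on its median, 2076 genes rose and 2173 fell at the same adjusted p. The arrays of the ages did not overlap in 36.2% of genes, where chance gives 10%. By camera 19 of 26 lists were called, and with an estimated correlation 0 were called (9 at an unadjusted p under 0.05). All 19 also passed fry, which tests whether a list's genes move on balance in one direction and does not compare them with other genes, with adjusted p from 5.79e-06 to 0.0195. Olfactory receptor genes had a median of 0.17 in replicate 1 of 8 days and in replicate 2 of 16 days, against -0.05 to 0.03 in the other arrays, and without these 2 arrays 4518 genes were called. Without replicate 2 of 8 days 1855 genes fell.

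**Figure D2:**
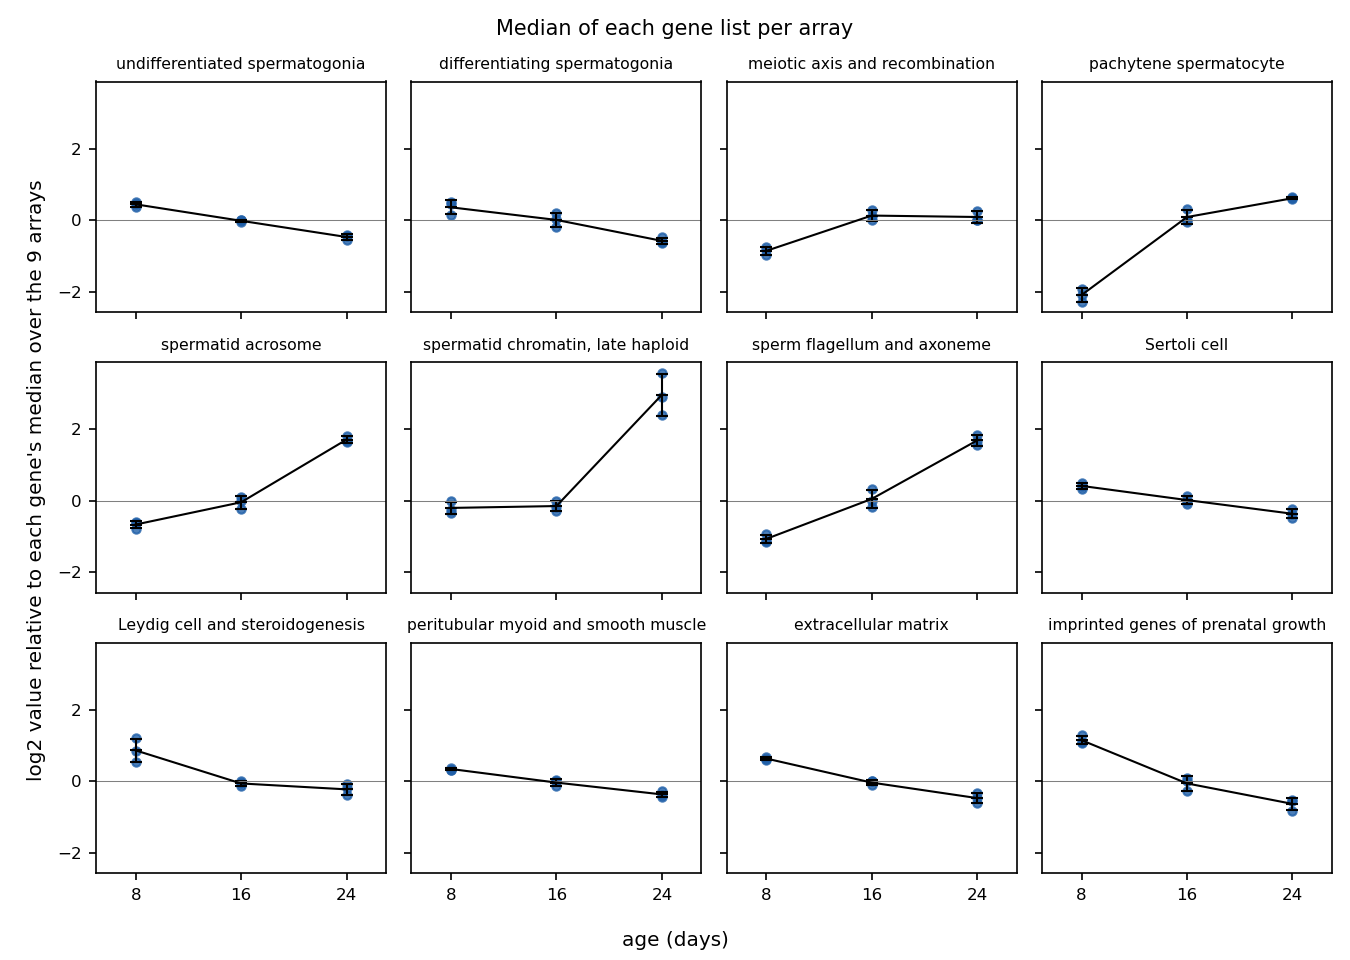
Median of the log2 values of each gene list per array (vertical axis, relative to each gene's median over the 9 arrays) against age in days (horizontal axis), for 12 lists. Blue points are arrays, and black marks are the mean and SD of 3 arrays; the mean for pachytene spermatocyte genes was -2.09 at 8 days and 0.61 at 24 days.

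Between 16 and 24 days, genes of haploid germ cells rose by up to 47.6-fold. The 6 largest rises were those of Smcp (gene ID 17235), a protein of the sperm mitochondrial capsule, by 5.57 ± 0.17 on the log2 scale, the acrosomal protein Acrv1 (gene ID 11451) by 5.36 ± 0.21, Stat4, a transcription factor also known from interleukin signalling, by 5.13 ± 0.17, Prm1 by 5.07 ± 0.22, the sperm protein Llcfc1 by 4.93 ± 0.20 and the allantoicase Allc by 4.89 ± 0.23. The 6 largest falls by the same rule were smaller, at -1.48 ± 0.21 for Dlk1, an imprinted ligand of the Notch family, -1.37 ± 0.45 for the pantetheinase Vnn1, -1.28 ± 0.27 for the small Cajal body RNA Scarna13, -1.25 ± 0.22 for Rasgrp1, an activator of Ras, -1.21 ± 0.23 for Zim1 and -1.19 ± 0.24 for Fam171b. With a block on the 6 numbered arrays Scarna13 changed by -0.85 and its call was lost (adjusted p 0.0752). The adjusted p of Vnn1, 0.0426, became 0.137 at its highest when 1 array was left out, and its change became -0.86 without replicate 1 of 24 days.

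Nearly all measured genes of sperm structures rose. Of 39 flagellum and axoneme genes, 38 rose, with a median of 1.77 relative to all genes, and the count was the same adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). Akap4, the main protein of the fibrous sheath, rose by 4.39 ± 0.22, and Cabyr, a calcium-binding sheath protein, by 4.23 ± 0.14. Of 23 genes of spermatid chromatin and late haploid transcripts, 22 rose, as many as adjusted over the list alone (median 3.02; adjusted p = 0.117 with an estimated correlation). Tnp1 (gene ID 21958) rose by 2.81 ± 0.33 and the sperm glyceraldehyde phosphate dehydrogenase Gapdhs by 4.18 ± 0.21. Of 23 acrosome genes, 22 rose, as many as adjusted over the list alone (median 1.80; adjusted p = 0.117 with an estimated correlation), with Spaca7 rising by 4.08 ± 0.20 and the capping protein Capza3 by 3.44 ± 0.20. Of 19 transcription regulators, 12 rose and 1 fell (14 and 2 adjusted over the list alone; median 0.78; adjusted p = 0.117 with an estimated correlation). Spz1, a testis transcription factor, rose by 4.42 ± 0.19 and Fhl5, a partner of the regulator Crem, by 3.62 ± 0.21.

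The genes of spermatocytes were divided over this interval. Of 25 pachytene genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone; median 0.72; adjusted p = 0.117 with an estimated correlation). The phosphoglycerate kinase Pgk2 rose by 2.90 ± 0.27, the axonemal protein Spag6 by 2.83 ± 0.12 and the cyclin Ccna1 by 2.22 ± 0.27. Of 20 metabolic isoforms 14 rose (16 adjusted over the list alone; median 0.88; adjusted p = 0.117 with an estimated correlation), including Aldoart2, a retrocopy of an aldolase, by 2.15 ± 0.27, and Ldhc rose by 0.72 ± 0.11. The list of the meiotic axis, synapsis and recombination was not called (camera adjusted p 0.485), with 5 genes that rose and 6 that fell of 36, as adjusted over the list alone. Its median was -0.10 and its mean -0.08, but 0.07 relative to all genes. Syce1, a component of the synaptonemal complex, rose by 0.73 ± 0.12 and Mei1 fell by 0.65 ± 0.15. The change was 0.03 ± 0.20 for Sycp3 (adjusted p 0.924), 0.29 ± 0.13 for Piwil1 (adjusted p 0.105) and 0.26 ± 0.15 for the testis linker histone H1f6 (adjusted p 0.186). Piwil1 passed the test without replicate 2 of 16 days (adjusted p 0.0257), and H1f6 passed it without the 2 arrays with raised olfactory receptor genes (adjusted p 0.0203). In the piRNA pathway 5 of 20 genes rose and 3 fell, as adjusted over the list alone, and the list was not called (camera adjusted p 0.0796), though it was without replicate 2 of 16 days (adjusted p 0.0306).

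Spermatogonial genes continued to fall. Of 19 genes of undifferentiated spermatogonia 13 fell, as many as adjusted over the list alone, with a median of -0.36, or -0.21 without replicate 2 of 24 days (adjusted p = 0.289 with an estimated correlation). Sall4 fell by 0.92 ± 0.14, Ret, the receptor for the stem cell factor GDNF, fell by 0.91 ± 0.17 and Zbtb16 fell by 0.86 ± 0.20. Of 15 genes of differentiating spermatogonia 12 fell and 1 rose, as adjusted over the list alone (median -0.47; adjusted p = 0.425 with an estimated correlation). With centred arrays 10 genes of the undifferentiated and 9 of the differentiating list fell, and 1 of each rose. Stra8 fell by 0.80 ± 0.19, Dmrt1, which holds back entry into meiosis, fell by 0.80 ± 0.16 and the transcription factor subunit Taf4b fell by 0.72 ± 0.09. Kit fell by 0.66 ± 0.17 (adjusted p 0.0146), a call that was lost without replicate 1 of 16 days or replicate 1 of 24 days (adjusted p up to 0.0622).

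Somatic and growth groups also fell. Of 29 extracellular matrix genes 21 fell and 1 rose (22 and 1 adjusted over the list alone), or 15 fell when each array was centred on its median (median -0.28; adjusted p = 0.425 with an estimated correlation). Fibronectin, Fn1, fell by 0.96 ± 0.18 and fibulin, Fbln1, fell by 0.70 ± 0.10. Of 15 imprinted genes 10 fell (13 adjusted over the list alone), or 6 with centred arrays (median -0.42; adjusted p = 0.425 with an estimated correlation), and the growth factor Igf2 fell by 1.05 ± 0.16. Of 35 X-linked housekeeping genes 21 fell (24 adjusted over the list alone), or 15 with centred arrays (median -0.36; adjusted p = 0.643 with an estimated correlation). Ogt, which adds N-acetylglucosamine to proteins, fell by 0.89 ± 0.13 and Taf1, a subunit of the general factor TFIID, fell by 0.79 ± 0.19. Of 16 immediate early and heat shock genes 11 fell (12 adjusted over the list alone), or 8 with centred arrays (median -0.32; adjusted p = 0.117 with an estimated correlation), and the transcription factor Egr1 fell by 0.84 ± 0.09. Of 19 Sertoli cell genes 8 fell (15 adjusted over the list alone), or 6 with centred arrays, with a median of -0.22 that ranged from -0.36 without replicate 2 to -0.13 without replicate 3 of 16 days (adjusted p = 0.539 with an estimated correlation). With the olfactory receptor covariate the medians of the X-linked housekeeping, imprinted and Sertoli cell lists were -0.62, -0.67 and -0.37, and with a block on the 6 numbered arrays that of the Sertoli cell list was -0.14. Sox9 and Wt1, transcription factors of Sertoli cells, changed by -0.67 ± 0.12 and -0.61 ± 0.14, and the change of Amh was -0.65 ± 0.25 (adjusted p 0.0726), which passed the test without replicate 2 of 8 days (adjusted p 0.00732).

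In the remaining groups, genes moved in both directions or only in part. Of 12 myoid and smooth muscle genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), and the list's camera adjusted p of 0.0497 rose as high as 0.0893 with 1 array left out and to 0.530 with an estimated correlation. Its median was -0.15, -0.24 without replicate 2 of 24 days, -0.26 with the olfactory receptor covariate, and -0.10 with a block on the 6 numbered arrays, where the call was lost, as it was against random lists of the same size (adjusted p 0.0764). The smooth muscle actin Acta2 fell by 0.61 ± 0.11 and the enteric actin Actg2 rose by 1.82 ± 0.23. The Leydig cell list was not called (camera adjusted p 0.836), with a median of -0.04 relative to all genes, or -0.20 as measured, where the mean was 0.04, and 2 of its 13 genes rose and 4 fell, as adjusted over the list alone. The endothelial list, with 5 of 16 that fell (6 adjusted over the list alone), the partners of the germ cell isoforms, with 9 of 19 that fell and 2 that rose (10 and 2 adjusted over the list alone), and cholesterol synthesis, with 6 of 19 that fell and 3 that rose (8 and 3 adjusted over the list alone), were not called (camera adjusted p 0.116, 0.0977 and 0.459). The partner list was called without replicate 2 of 16 days (adjusted p 0.0184). With centred arrays 4 myoid genes fell and 1 rose, 2 Leydig cell genes fell and 2 rose, 3 endothelial genes fell and 1 rose, 7 partners fell and 2 rose, and 5 cholesterol synthesis genes fell and 2 rose. Fdft1, which makes squalene, rose by 1.01 ± 0.12.

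In all, 6645 genes differed between 24 and 16 days by limma, of which 2641 rose and 4004 fell, and 1072 rose and 29 fell by at least 2-fold. When each array was centred on its median, 2861 rose and 1927 fell. The arrays of the ages did not overlap in 55.6% of genes, where chance gives 10%. By camera 14 of 26 lists were called, all of which passed fry (adjusted p from 7.48e-05 to 0.0270), and 0 were called with an estimated correlation (7 at an unadjusted p under 0.05). The count was 3669 without replicate 1 of 16 days, in which interferon-inducible genes were high, 3811 without replicate 1 of 24 days, and 8698 without the 2 arrays with raised olfactory receptor genes. The falls alone numbered 1672, 1764 and 2616 without replicate 1 of 16 days, replicate 1 of 24 days and replicate 3 of 16 days, and 2423 with blanks left missing.

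Across the whole span from 8 to 24 days, the 6 largest rises lay between 78.8-fold and 123-fold, and the largest fall was 10.5-fold. Spata4 rose by 6.94 ± 0.13, Gk2 by 6.90 ± 0.18, Crisp2 by 6.89 ± 0.16, Ube2d2b by 6.59 ± 0.16, Fbp1 by 6.32 ± 0.15 and Pabpc2 by 6.30 ± 0.22. Zim1 fell by 3.39 ± 0.23, Sel1l3 fell by 3.35 ± 0.16, Hsd17b3 fell by 3.24 ± 0.30, Mest fell by 2.88 ± 0.20, Plagl1 fell by 2.77 ± 0.27 and the gelatinase Mmp2 fell by 2.72 ± 0.14. All of these values are differences of log2 means with standard errors, from 3 arrays per age, and the limma adjusted p lay between 1.96e-09 and 1.54e-05.

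All 23 measured acrosome genes rose from 8 to 24 days, as did 38 of 39 flagellum genes, 22 of 23 spermatid chromatin genes, 24 of 25 pachytene genes and 19 of 20 metabolic isoforms, with the same counts adjusted over the list alone. Their medians relative to all genes were 3.33, 3.72, 3.18, 3.19 and 3.09, and their adjusted p with an estimated correlation was 0.105, 0.105, 0.173, 0.0873 and 0.0873. Adam3, a sperm surface protein, rose by 5.59 ± 0.32, Zpbp2 by 5.19 ± 0.21 and Spag17 by 4.98 ± 0.20. In the meiotic axis list 25 of 36 rose and 6 fell, as adjusted over the list alone (median 1.23; adjusted p = 0.173 with an estimated correlation). In the piRNA pathway 16 of 20 rose and 3 fell (17 and 3 adjusted over the list alone; median 1.28; adjusted p = 0.173 with an estimated correlation), and among the regulators 14 of 19 rose and 2 fell, as adjusted over the list alone (median 2.03; adjusted p = 0.0873 with an estimated correlation). Tdrd6 rose by 5.13 ± 0.23, Spo11 by 3.12 ± 0.17 and Spz1 by 4.53 ± 0.19.

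Of 29 extracellular matrix genes 28 fell from 8 to 24 days, of 35 X-linked housekeeping genes 31, of 15 imprinted genes 14, of 16 immediate early and heat shock genes 14 and of 16 endothelial genes 13, against 28, 32, 14, 14 and 13 adjusted over the list alone. Their medians were -0.91, -0.86, -1.68, -0.64 and -0.46, and their adjusted p with an estimated correlation was 0.173, 0.365, 0.217, 0.0873 and 0.0873. Fn1 fell by 1.93 ± 0.18, Rps4x fell by 1.60 ± 0.17, the transcription factor Jun fell by 1.28 ± 0.15 and Cdh5 fell by 1.62 ± 0.15. In the spermatogonial lists 16 of 19 undifferentiated and 13 of 15 differentiating genes fell and 1 of each rose (17 and 13 fell adjusted over the list alone), with medians of -0.76 and -0.78 (adjusted p = 0.173 and 0.322 with an estimated correlation). Sall4 fell by 1.65 ± 0.14, Ret fell by 1.62 ± 0.17, Ccnd2 fell by 1.81 ± 0.14 and Kit fell by 1.15 ± 0.17.

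Of 19 Sertoli cell genes 16 fell (17 adjusted over the list alone; median -0.79; adjusted p = 0.322 with an estimated correlation), with changes of -2.36 ± 0.25 for Amh and -1.56 ± 0.11 for Kitl. In the Leydig cell list 11 of 13 fell and 1 rose, as adjusted over the list alone (median -0.98; adjusted p = 0.256 with an estimated correlation). The member that rose was Hsd3b6, an isoform typical of adult Leydig cells, by 2.24 ± 0.52. In the myoid list 11 of 12 fell and 1 rose, as adjusted over the list alone (median -0.60; adjusted p = 0.256 with an estimated correlation). Of 19 partners of the germ cell isoforms 17 fell and 2 rose, as adjusted over the list alone (median -0.69; adjusted p = 0.353 with an estimated correlation), and Ldha rose by 2.10 ± 0.14. Of 19 cholesterol synthesis genes 12 fell and 1 rose, as adjusted over the list alone (median -0.35), but the camera adjusted p of 0.0492 rose as high as 0.0940 with 1 array left out and to 0.431 with an estimated correlation. With centred arrays, falls numbered 13 in the Sertoli cell list, 9 in the Leydig cell list, 11 in the myoid list, 15 among the partners and 9 in cholesterol synthesis. The cholesterol synthesis median was -0.56 with array weights and -0.61 with the olfactory receptor covariate (adjusted p 0.0246 and 0.0109). The sterol regulator Srebf2 fell by 1.32 ± 0.13.

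The 8 to 24 day comparison called 10840 genes by limma, of which 3825 rose and 7015 fell, and 1937 rose and 1427 fell by at least 2-fold. Centring each array on its median moved all genes by 0.12 on the log2 scale and gave 4389 that rose and 5236 that fell. The arrays of the ages did not overlap in 65.5% of genes, where chance gives 10%. By camera 20 of 26 lists were called, all of which passed fry (adjusted p from 1.09e-06 to 0.000627), and 0 were called with an estimated correlation (7 at an unadjusted p under 0.05). Without the 2 arrays with raised olfactory receptor genes 11153 genes were called. Over the 3 ages together, limma's moderated F called 10104 genes.

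Groups that the camera test called in none of the 3 comparisons were those of macrophages, epididymis, adipocytes, Y-linked genes, blood-testis barrier junctions and DNA replication. Of 20 macrophage and immune genes 3 rose and 7 fell from 8 to 24 days, as adjusted over the list alone, or 3 and 3 with centred arrays (camera adjusted p 0.938), and the median was -0.10 relative to all genes, or -0.28 as measured, where the mean was 0.07. Fcgr3, an immunoglobulin receptor, rose by 2.21 ± 0.23, Aif1, a calcium-binding protein of macrophages, by 2.09 ± 0.18 and the class II gene H2-Ab1 by 1.78 ± 0.21. Of 14 blood-testis barrier genes 10 fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p 0.106), with a change of 2.05 ± 0.16 for Nectin3, an adhesion molecule of spermatids, and of -1.19 ± 0.15 for the connexin Gja1. Of 32 DNA replication genes 17 fell and 4 rose, as adjusted over the list alone (camera adjusted p 0.148), and the helicase subunit Mcm2 fell by 1.59 ± 0.12. The list was called without replicate 1 of 8 days (adjusted p 0.0245). By fry the adjusted p was 0.000737 for the barrier and 0.0128 for the DNA replication list, and against random lists of the same size it was 0.0128 and 0.00598. Of 8 Y-linked genes 3 fell and 2 rose, as adjusted over the list alone (camera adjusted p 0.696), with a change of -1.19 ± 0.15 for the demethylase Kdm5d. Of 10 adipocyte genes 3 fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p 0.826), and of 11 epididymal genes 1 fell, Wfdc2 (0 adjusted over the list alone; camera adjusted p 0.910). The adjusted p of Wfdc2 was 0.0192, and it was 0.0594 without replicate 2 of 24 days and 0.0599 with centred arrays. With centred arrays 7 barrier genes fell and 2 rose, 15 DNA replication genes fell and 4 rose, and 2 adipocyte genes fell and 1 rose. Only 3 red blood cell genes had a value, too few to test, and their median was -0.04.

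The change over the second interval differed from that over the first, by a direct limma test of the difference, in 1072 genes, of which 611 had the higher and 461 the lower change in the second interval. The stage genes of spermatids changed more between 16 and 24 days, with a difference of 5.16 ± 0.38 for Prm1 (adjusted p 6.17e-05), 5.35 ± 0.36 for Acrv1 (adjusted p 3.56e-05) and 2.78 ± 0.58 for Tnp1 (adjusted p 0.0198). Those of pachytene spermatocytes changed more between 8 and 16 days, with -4.17 ± 0.19 for Ldhc (adjusted p 7.46e-06), -3.40 ± 0.22 for Piwil1 (adjusted p 3.34e-05) and -2.19 ± 0.26 for H1f6 (adjusted p 0.000747). The difference did not pass the limma test for Amh, Zbtb16, Kit, Stra8 and Sycp3, whose adjusted p was 0.272, 0.923, 0.799, 0.395 and 0.0618. The number was 613 without replicate 1 of 16 days and 1063 without the 2 arrays with raised olfactory receptor genes.

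Genes called in both intervals mostly kept their direction. In both intervals 1199 genes rose and 1679 fell, where 274 and 571 would be shared by independent lists and 61 and 152 in simulated data with no change other than the shared 16 day arrays. Another 50 rose and then fell, and 56 fell and then rose, against 416 and 377 for independent lists and 1112 and 1078 in the simulated data. In the simulated data the same number of genes per direction was taken by rank of limma's t, whether or not they passed the threshold. The simulated counts are therefore not numbers of called genes. The 16 day arrays enter both intervals with opposite sign, and 3 arrays are too few to split between the intervals. Centring each array on its median cut the falls for 24 versus 16 days from 4004 to 1927. The overlap was not computed with centred arrays, so how far the number of shared falls depends on this scaling is not known.

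Genes of the X chromosome fell more than autosomal genes by camera with its preset correlation of 0.01, but not with an estimated correlation. From 8 to 24 days, 403 of 739 X-linked genes fell, or 54.5%, against 34.5% of 19103 autosomal genes, and with each array centred on its median the shares were 45.6% and 25.6%. The median change of X-linked genes was -0.18, -0.26 and -0.43 for 16 versus 8, 24 versus 16 and 24 versus 8 days, against -0.02, -0.16 and -0.17 for autosomal genes. The camera p was 1.15e-06, 0.0132 and 0.000174, and the p with an estimated correlation was 0.0866, 0.337 and 0.165. For 24 versus 16 days the call was lost without replicate 3 of 16 days (p 0.0541) or replicate 3 of 24 days (p 0.1003), and over all alternatives its p ranged from 0.000371 to 0.337. The X-linked minus autosomal median for 16 versus 8 days was -0.16 over all arrays and -0.10 without replicate 2 of 8 days or without replicate 2 of 16 days, and that for 24 versus 16 days was -0.10 over all arrays and -0.19 with the olfactory receptor covariate. The difference between the intervals was 0.08 (camera p 0.0134), and it was -0.0022 without replicate 2 of 16 days.

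**Figure D3:**
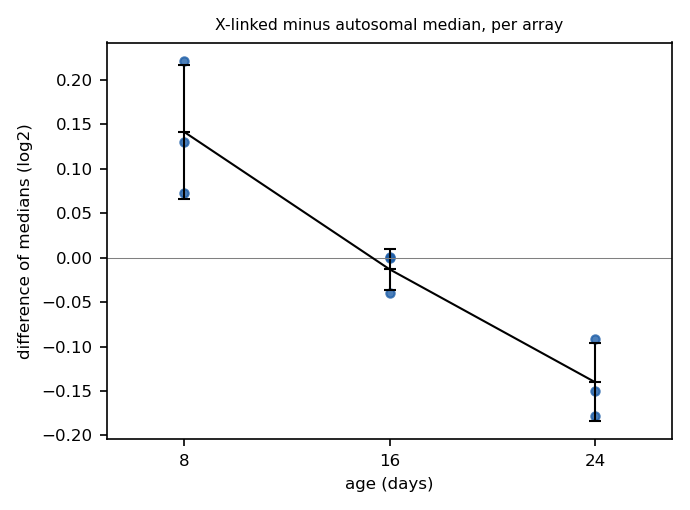
Median log2 value of X-linked genes minus that of autosomal genes on each array (vertical axis) against age in days (horizontal axis). Blue points are arrays, and black marks are the mean and SD of 3 arrays; the 3 arrays of 24 days lie between -0.178 and -0.092 and those of 8 days between 0.073 and 0.222.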

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

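The tests of developmental lead, of immune cells, of array quality and of a trend that olfactory receptor genes follow were chosen only after the results they address were seen, and the list of interferon-inducible genes was written after their pattern was seen.

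A direct test found that 611 genes had a higher and 461 a lower change in the second interval than in the first. These were 344 and 269 without replicate 1 of 16 days, the higher ones numbered 391 without replicate 3 of 16 days, and the lower ones 735 with the olfactory receptor covariate. By the same kind of test on lists, with medians relative to all genes, the second interval exceeded the first by 2.89 for spermatid chromatin and late haploid transcripts (adjusted p = 0.137 with an estimated correlation), 1.36 for the acrosome (0.520 as that p) and 0.21 for the flagellum (0.707 as that p). It was lower by a median of -1.78 for pachytene genes, -1.19 for germ cell metabolic isoforms, -0.87 for the meiotic axis and -0.73 for the piRNA pathway (adjusted p = 0.137, 0.520, 0.137 and 0.209 with an estimated correlation). Groups that fell less in the second interval were Leydig cell genes at 1.07, endothelial genes at 0.35, extracellular matrix at 0.25, imprinted genes at 0.36 and cholesterol synthesis at 0.22 (adjusted p = 0.187, 0.137, 0.636, 0.617 and 0.636 with an estimated correlation). Members that passed on their own numbered 14 higher and 11 lower of 39 for the flagellum, and 11 and 3 of 23 for the acrosome. Higher members numbered 18 of 23 for spermatid chromatin, 2 of 13 for Leydig, 2 of 15 for imprinted, 1 of 29 for matrix and 1 of 19 for cholesterol synthesis genes. By limma 0 of 16 endothelial genes passed (2 at an unadjusted p under 0.05). Lower members numbered 18 of 25 for pachytene genes, where 1 was higher, and 8 of 20 for metabolic isoforms, where 3 were higher. They numbered 17 of 36 for the meiotic axis and 6 of 20 for the piRNA pathway. Of the 12 lists, fry called 8, and not the flagellum, matrix, imprinted and cholesterol lists (adjusted p 0.273, 0.335, 0.335 and 0.461). Without replicate 2 of 16 days the Leydig, matrix, imprinted and cholesterol differences were 0.59, 0.13, 0.15 and 0.06, and the calls of the last 3 were lost. The imprinted difference was 0.59 without replicate 3 of 16 days and 0.57 without replicate 1 of 8 days. The flagellum difference was -0.04 without replicate 3 of 16 days, 0.07 without replicate 1 and 0.54 without replicate 2, and 0.12 without replicate 1 of 24 days. With only rows with 1 blank cell the acrosome and flagellum differences were 0.62 and 0.11, the latter no longer called (adjusted p 0.129). With the olfactory receptor covariate the Leydig, imprinted and cholesterol differences were 0.60, 0.20 and 0.02, and the calls of the last 2 were lost. Without the 2 arrays with raised olfactory receptor genes the metabolic isoform and piRNA differences were -0.78 and -0.44, the matrix, imprinted and cholesterol differences were 0.14, 0.15 and 0.09, and the calls of these last 3 were lost. Outside the gene test, in rows with several genes or none, 2422 of 7035 were called from 8 to 24 days, 787 higher and 1635 lower.

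Each of the age comparisons had 10 splits of its 6 arrays, too few for a share under 0.05. The real counts were 4914, 6645 and 10840, and the highest of the other splits gave 1, 1 and 0. Among 100 splits of the 9 arrays into 3 groups, the real split alone, 1 split, called as many as 10104 genes by the F test. The highest other gave 6138. This argues against a random division of the arrays as the source of the count. It says nothing about single genes, and mixed-age groups carry the age differences in their spread, which lowers the other counts. For the difference between intervals 4 of 100 splits, the real one included, gave 1072 or more, and the highest other gave 9221. These splits do not test that difference, since groups of mixed ages carry the age differences in their spread, and all 3 splits above the real count had the 3 arrays of 8 or of 24 days as the middle group and measured the difference between ages.

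Olfactory receptor genes, which mouse testis expresses at most in part, had a median of 0.17 in replicate 1 of 8 days and 0.17 in replicate 2 of 16 days, and the deviations of these 2 arrays from their age means correlated across genes at 0.596, where genes are not independent replicates. Whether replicate 1 of 8 days was developmentally ahead cannot be told apart, since the called lists disagreed. Relative to all genes, 2 of 7 lists that rise to 16 days lay above its mates, a share of 0.286, and 11 of 12 that fall lay below. Against the mates its meiotic axis genes had a median of -0.256 and its flagellum genes one of 0.213. In replicate 2 of 16 days all 6 lists that rise to 24 days lay above and all 8 that fall lay below its mates, a share of 1 for both. Its flagellum median was 0.408. A sample that was ahead would give this, but the lists are not independent. Among the 6, spermatid chromatin lay 0.185 above relative to all genes, though 0 of its 23 genes rose from 8 to 16 days. The counts therefore do not separate a lead from an array-wide difference. A first test had used a single list for each array, and the test over all called lists took its place after list medians had been seen. By the first test a lead of replicate 1 of 8 days had been argued against. An array-wide difference left by the normalization remains open and cannot be told apart, since rows without a gene lay 0.105 and 0.0852 above their mates in these arrays, where at least 0.1 in both was needed, and between -0.07 and 0.01 in the other 7. Age is shared within each comparison, and differences between animals were not tested.

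Interferon-inducible genes were high in replicate 1 of 16 days, where 42 of 46 measured genes lay above both mates, 23 of them by more than 1, with a median of 1.15. More macrophages are argued against by the macrophage and immune list, whose 20 members went both ways around a median of 0.0384 above the mates. Of these, 12 lay above and 8 below, from -0.32 for Cx3cr1 to 0.65 for H2-Aa, with an SD of 0.257. All 20 lay under the median of 1.15 of the interferon-inducible genes, which does not by itself bear on cell number. The list holds no markers chosen for lymphocytes, so that a gain of these cells remains open. Large deviations over all genes, as a poor array may give, are argued against by their spread, which was 0.713 of that of the mate with the smaller spread. A position between 2 opposed mates also lowers this spread, and the mates correlated at r -0.318 across genes. Other faults of the array therefore remain open. The design names no difference among arrays of the same age, so that no biological explanation beyond the macrophage content was tested.

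X-linked genes fell more than autosomal genes from 8 to 24 days, though not past the threshold with an estimated correlation (p 0.165). A different mix of gene functions is argued against, for ubiquitous complexes, by their 12 X-linked members, which lay -0.833 from 363 autosomal members. Of the X-linked members 11 fell, or 91.7%, against 35.3% of the autosomal members. The permutation p was 1e-05, the smallest that the permutations can give, but it treats genes as independent. The X-linked housekeeping list, which shares some of these members, had an estimated correlation of 0.719. Ribosomal protein kinases were left out of the complexes only after the result was seen. An array-wide trend that olfactory receptor genes follow is argued against as the whole cause, since with their median as a covariate the difference was -0.365 (camera p 2.29e-05 with the preset correlation, and from 2.29e-05 to 0.165 over all alternatives). A shift of a whole array cancels in this difference, so that centring the arrays tests nothing here. Other effects of the normalization, such as one that depends on the signal, remain open because the values hold no expression level, as do age-linked biological explanations, such as silencing of the X chromosome in meiosis or a smaller share of somatic cells, which may also act together and were not tested.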

How the results depend on the processing

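The alternatives with blanks left missing, only rows with 1 blank, robust eBayes, the olfactory receptor covariate, the 2 arrays left out and random lists were chosen only after the data were seen. Quantile normalization, both filters on dim genes, log2(value + 16), eBayes with trend and random lists matched on expression were not run, because centred log2 values hold no expression level and quantile normalization would force 1 distribution on differences. Where a cause is not stated, the cause was not tested. Centred values also leave signal over background unknown.

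With an estimated correlation, camera called 0 lists in each of the 3 comparisons and in the difference between intervals (9, 7, 7 and 6 at an unadjusted p under 0.05, and 19, 17, 24 and 8 by fry), and the X chromosome medians of -0.159, -0.102, -0.256 and 0.0793 were no longer past the threshold. A minimum of 2-fold gave 954, 1101 and 3364 genes, and treat gave 696, 793 and 3578, as stricter criteria. Same-numbered arrays were not all positively correlated (r of deviations from -0.461 to 0.453 across genes). This gives no evidence that the numbers pair samples, but deviations from a mean of 3 arrays cannot exclude it. A block on the 6 numbered arrays, with fewer samples, gave 1971, 1294 and 550 genes for 16 versus 8 days, 24 versus 16 days and the difference between intervals, 5934 by the F test and an X chromosome median of -0.0599 for 24 versus 16 days. A block on all 9 arrays gave 4501, 5864, 10456, 1011 and 9613. For the X chromosome difference between intervals, array weights gave 0.0298, the olfactory receptor covariate 0.0109 and leaving out the 2 arrays 0.0340, none past the threshold. The block on the 6 numbered arrays gave 0.184 instead (camera p 1.79e-05 with the preset correlation). Against random lists of the same size, a test that takes no account of correlation among genes, 12 list calls were gained over the 3 comparisons and the difference between intervals and 1 was lost. Under the other alternatives run that kept all arrays, the total number of genes called in each comparison stayed within 1.5 times that reported. Counts by direction did not, with 1927 falls for 24 versus 16 days when each array was centred and 2423 with blanks left missing, in place of 4004, and 735 lower for the difference between intervals with the covariate, in place of 461.

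With 1 array left out, counts ranged from 3669 to 8070 for 24 versus 16 days and from 613 to 1047 for the difference between intervals. X chromosome medians ranged from -0.150 to -0.0705 for 24 versus 16 days and from -0.00221 to 0.160 for the difference, the lowest, reversed, without replicate 2 of 16 days. Without that replicate the differences for undifferentiated and differentiating spermatogonia were also reversed, with ranges of -0.223 to 0.0925 and -0.253 to 0.183 over the arrays left out. The flagellum difference ranged from -0.0437, reversed, without replicate 3 of 16 days to 0.538 without replicate 2. Of 356 named genes and lists with a test, 306 kept their side of the threshold in every fit with 1 array left out, 29 lost a call and 18 gained one in at least 1 of them, and the 3 lists named here were reversed and crossed the threshold. Values that were never called also changed sign in some of these fits, among them Acrv1 for 16 versus 8 days, from -0.0704 to 0.116.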

Other observations

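The gene families, rows and single arrays described here were all chosen only after the results were seen.

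Among 236 families of genes that share a symbol prefix, those of cilia and flagella rose from 8 to 24 days. Medians of families are as measured, not relative to all genes. In the Cfap family of cilia and flagella proteins 30 of 31 genes rose (median 2.90), in the Ift family, which carries cargo along cilia, 14 of 14 rose (median 1.52), and in the Dnah family of axonemal dynein heavy chains 12 of 15 rose and 1 fell (median 2.88). The Ttll family, which modifies tubulin tails, had 10 of 12 that rose and 1 that fell (median 1.49), and the Dnajb family of chaperones 12 of 13 and 1 that fell (median 0.99). Families that fell were Adamts, secreted metalloproteases, with 14 of 18 (median -0.70), Sema, guidance molecules, with 16 of 20 and 1 that rose (median -0.71), Fzd, the Wnt receptors, with 10 of 11 (median -0.59), and the ribosomal protein families Rps and Rpl, with 19 of 31 and 23 of 36, where 2 Rpl genes rose (medians -0.41 and -0.37). Their camera adjusted p lay between 4.08e-21 and 0.0451, and with an estimated correlation the adjusted p of these families lay between 0.653 and 0.990.

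Some genes varied among arrays of the same age. The steroidogenic gene Cyp17a1 had values of -2.25, -0.20 and -2.32 at 16 days and 0.15, 0.00 and -2.17 at 24 days, in the order of replicates 1, 2 and 3. Tnp1 had values of 3.58, 2.90 and 1.85 at 24 days. The carbonic anhydrase Car3, abundant in fat and muscle, had values of 0.45, 0.04 and 2.28 at 8 days.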
